A study of Mus musculus with 6 samples.

How the data were processed

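RNA was measured in MIN6-4N, a mouse insulinoma line of pancreatic beta cells, after stable transfection with an empty expression plasmid or with the same plasmid carrying mouse Meg3, a maternally expressed long non-coding RNA. Per the labels' protocols, G418 selection at 750 µg/ml lasted 5 weeks before clones were taken, and the culture medium afterwards held 15% serum and 500 µg/ml G418. Per the same protocols, total RNA came from 3 independent cultures of 1 vector clone and 3 of 1 Meg3 clone, and 6 µg of each was labelled with biotin for an Affymetrix array. The 6 arrays form 2 groups, called vector and Meg3 here, of 3 replicates each. The labels name the Meg3 clone in more than 1 way, so it is called only the Meg3 clone. Their descriptions also speak of a sort of the cells, which no protocol mentions, so whether one was done is unknown. Because each group is 1 clone, p-values measure the spread between cultures of a clone, and an effect of the plasmid cannot be told apart from other differences between the clones.

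The authors deposited log2 values per probe set, made with RMA, and Partek is also named, per the submitters' processing notes. Versions and a genome build are not given in the sources used here. The deposited table holds 241419 probe sets on 6 arrays, with array medians from 7.02 to 7.19. Probe sets on this array design cover about an exon each, so a gene has many (median 8). The array annotation gave 1 gene symbol to 212097 probe sets, several to 4475 and none to 24847. Only the first kind was used for genes, and the rest were tested separately. The value of a gene was the mean log2 value of all its probe sets on an array, which gave 20416 genes. Symbols were updated through the gene table of the assembly GRCm38.p6, in which 20363 matched, 2742 of them through a synonym, and 53 did not. That table also gave chromosome membership and the order of genes. No coordinates are given, because the build behind the array annotation was not given. Arrays carry no read depth, and their number limits the precision.

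Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Meg3 minus vector, no covariates), with Benjamini-Hochberg adjustment over all 20416 genes. Genes with an adjusted p under 0.05 were called, and no filter on dim genes was applied. The groups' means and SDs are over 3 cultures, and errors given with a log2 difference are the moderated standard errors of that model. A log2 difference of at least 1 counted as 2-fold. For 34 gene lists written before the data were examined, camera with a preset inter-gene correlation of 0.01 was run, adjusted over the lists. Each list was also tested with an estimated correlation and with fry. Exact permutation tests of 3 against 3 arrays cannot give a two-sided p under 0.1. The steps were tested on simulated data built on these arrays. In that simulation of Meg3 minus vector over 20416 genes, 59% of 100 genes changed by 1 on the log2 scale were called, 89% of 100 genes changed by 2 were called, and 3 unchanged genes were called. Its noise was drawn independently for each gene, so genes did not vary together as on the real arrays, and these shares need not hold there.

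The genes named were chosen by a rule also written beforehand. It took Meg3 and a fixed set of genes whatever their values (Met, Men1, Cdkn1a, Cdkn1b, Cdkn2c, Gdf15, Ins2, Pdx1, Mafa and Dlk1; Trp53 and Ins1 were in the set and are not analysed here). It added the 12 largest positive and 12 largest negative differences among called genes whose groups did not overlap and whose higher mean exceeded the median of all genes. Left out were predicted or clone-derived gene names (Gm with digits, names ending in Rik, LOC names, BC and AK accessions) and olfactory, vomeronasal, immunoglobulin and histone cluster genes. From each list described it took up to 4 members, the 2 called higher and the 2 called lower with the largest differences, or the 2 with the highest mean level where none was called. Genes outside this rule are marked as chosen after their values were seen.

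Alternatives planned beforehand were a replicate block, centring each array on its median, quantile normalization applied again, leaving out the dimmest 30% of genes, the brightest probe set of each gene, eBayes with trend and robust estimation, an ordinary linear model, array weights, a test against a 1.5-fold difference, probe sets tested singly, and leaving out each array in turn. Alternatives chosen after seeing the data were leaving out vector replicate 2 and Meg3 replicate 1 together, subtracting the median difference of each chromosome, the HGF and MET signalling list without Met, and the MHC class I presentation list without H2 genes. For chromosomes, genes above the median of all genes were used (10179 genes on 20 chromosomes), in blocks of 50 neighbouring genes, and each chromosome's median was set beside 10000 random sets of as many genes matched on mean level.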

Results

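Expression was profiled on 6 arrays in MIN6-4N cells, a mouse pancreatic beta cell line, with 3 cultures of a vector clone and 3 of a clone stably transfected with Meg3. Meg3 is an imprinted non-coding RNA gene, and the comparison asks which genes differ in level when it is overexpressed in beta cells. Between pairs of arrays the gene values correlated at 0.968 or more. Vector replicate 2 and Meg3 replicate 1 stood apart from the remaining arrays. Their probe set values had an SD of 0.85 and 0.63 (log2) around the median of the other arrays, against 0.42 to 0.48 for the remaining 4.

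Meg3 itself was higher in the Meg3 clone. Its mean log2 value was 5.84 ± 0.19 (SD, n = 3) in the vector clone and 7.56 ± 0.34 (SD, n = 3) in the Meg3 clone, a 3.30-fold difference (log2 difference 1.72, SE 0.19; limma, Benjamini-Hochberg adjusted p = 0.00756). All 3 Meg3 cultures lay above all 3 vector cultures. Of the 5 Meg3 probe sets, 4 were higher, by 1.36 to 3.34 on the log2 scale, and the last differed by -0.22; tested singly, 0 of the 5 were called by limma (lowest adjusted p 0.220). Other listed and measured genes of the same imprinted domain on chromosome 12 were not called. All but Dlk1 had mean log2 values under the median of all genes (6.66) in both clones, so little can be read from them. Dlk1, which encodes a Notch-related membrane protein, differed by 0.05 (SE 0.15). The 20 nearest expressed neighbours of Meg3 had a median log2 difference of 0.04, and 0 of them were called (limma). An exact permutation test for Meg3 gave p = 0.1, the smallest that 3 against 3 arrays allow.

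**Figure D1:**
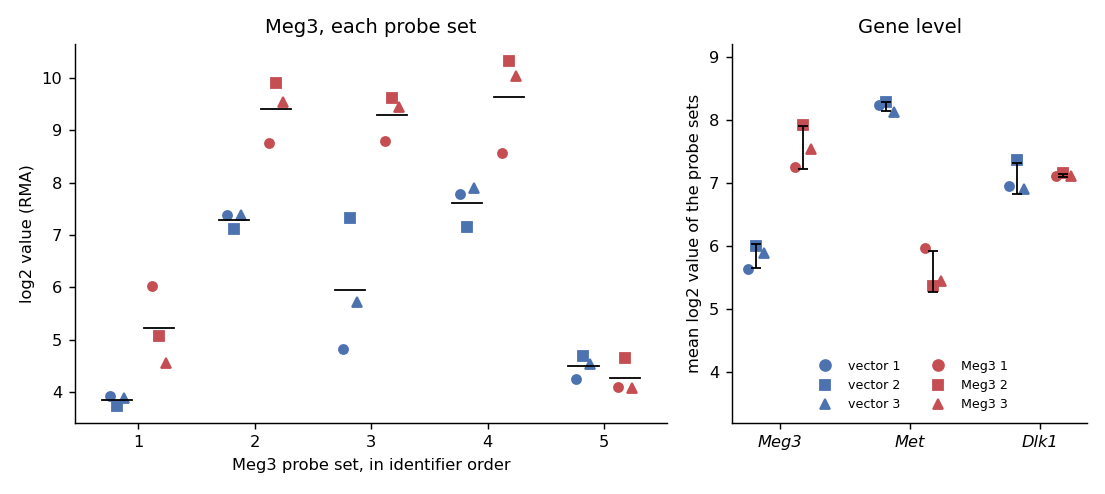
The left panel plots the log2 value of each of the 5 Meg3 probe sets on the 6 arrays, with a line at each group mean. The right panel plots the gene-level log2 values of Meg3, Met and Dlk1, with bars of 1 SD around each group mean; the Meg3 clone averages 7.56 for Meg3 against 5.84 in the vector clone, and 5.59 for Met against 8.21.

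Across the genome, 136 of 20416 genes were called (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 41 were higher and 95 lower in the Meg3 clone, and 90 differed at least 2-fold, 23 of them higher and 67 lower. At an unadjusted p under 0.05 there were 547 higher and 874 lower genes. The groups did not overlap for 12.8% of genes, where chance gives 10%. The median log2 difference of all genes was 0.01. Without vector replicate 2 and Meg3 replicate 1, a setting chosen after seeing the data, 292 genes were higher and 819 lower, and all 136 genes were among them in the same direction. Those arrays were picked for their spread, and the rest also entered the main fit. The calls and list results of this setting, here and below, are therefore no independent support. Leaving out single arrays gave from 8 higher and 14 lower genes (without Meg3 replicate 3) to 78 higher and 271 lower (without vector replicate 2).

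**Figure D2:**
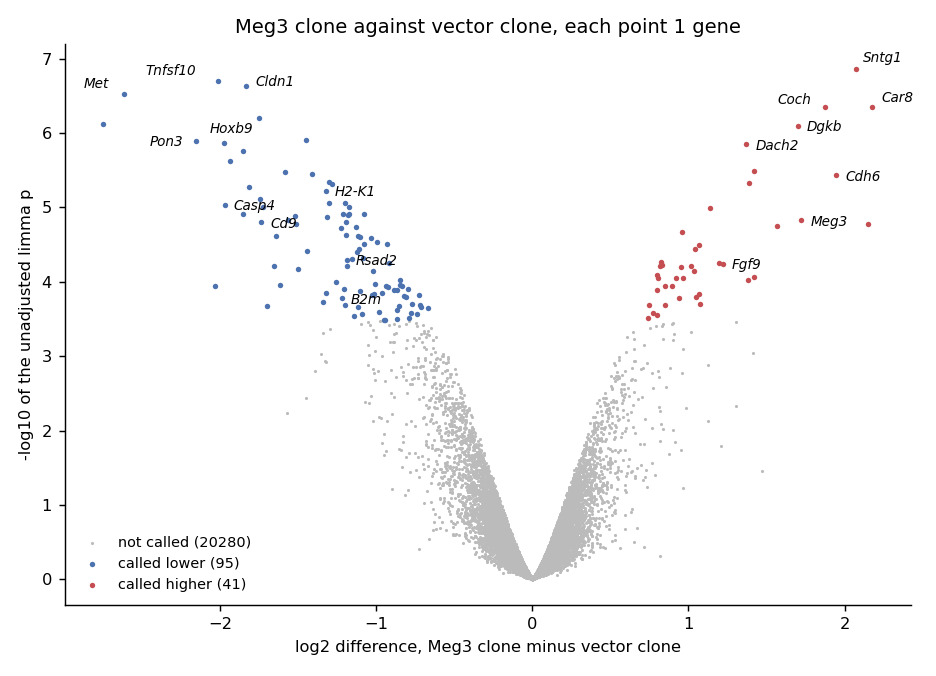
Each point is 1 of 20416 genes, with the log2 difference (Meg3 clone minus vector clone) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 95 genes called lower extend to larger differences than the 41 called higher, with Met at -2.62 and Car8 at 2.18.

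Met, the receptor tyrosine kinase for hepatocyte growth factor, was the lowest of the genes the naming rule selected. It fell from a mean log2 value of 8.21 ± 0.08 (SD, n = 3) to 5.59 ± 0.33 (SD, n = 3), a 6.13-fold difference (log2 difference -2.62, SE 0.17; limma adjusted p = 0.00150). A630095E13Rik, now named Pate14, which the rule leaves out for its clone-derived name, differed more (log2 difference -2.75, SE 0.20) and was chosen after its value was seen. All 20 Met probe sets were lower, by -3.88 to -0.89 on the log2 scale, and 1 was called when probe sets were tested singly. The list of HGF and MET signalling genes was lower as a whole (median -0.16, 17 members measured; camera adjusted p = 0.00550), with Met the 1 member called, and 2 were lower when adjusted over the list alone. That list's call was lost with an estimated correlation (adjusted p = 0.278 with an estimated correlation) and without Met (adjusted p = 0.0893), and also without vector replicate 3 (0.0868) or Meg3 replicate 1 (0.108). Vector replicate 2 and Meg3 replicate 1 read lower for it than the others of their group, by medians of -0.17 and -0.25, and without them its median was -0.03 (camera adjusted p = 0.00181). The gene of the ligand, Hgf, chosen after its value was seen, differed by 0.03 (SE 0.12). The 20 nearest expressed neighbours of Met had a median log2 difference of -0.06 with 0 called by limma. The caveolin gene Cav2, chosen after its value was seen, lies near Met but below the level set for expressed genes. Cav2 was lower (log2 difference -1.30, SE 0.12, limma adjusted p = 0.00446). Cav1, the other caveolin gene there, chosen likewise, was not called (-0.21, SE 0.16). Its mean log2 values were only 5.22 in the vector clone and 5.01 in the Meg3 clone, so this says little.

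Besides Met, the largest decreases among genes the naming rule selected were in genes of varied function. Pon3, a lactonase of the paraoxonase family, was 4.45-fold lower (log2 difference -2.15, SE 0.17), and the adhesion molecule gene Ceacam10 4.09-fold lower (-2.03, SE 0.29). Tnfsf10, which encodes the death ligand TRAIL, was 4.04-fold lower (-2.01, SE 0.13). Casp4, an inflammatory caspase, fell by 1.97 (SE 0.20) on the log2 scale, and the secretory vesicle GTPase gene Rab3c fell by 1.94 (SE 0.17). The tetraspanin gene Cd9 fell by 1.74 (SE 0.19), the protocadherin gene Pcdhb2 by 1.85 (SE 0.15), the kinase gene Nrk by 1.82 (SE 0.17) and the protein kinase D gene Prkd3 by 1.74 (SE 0.17). Their limma adjusted p-values ran from 0.00150 for Tnfsf10 to 0.0250 for Ceacam10. For Prkd3, 19 of 20 probe sets were lower, but the brightest differed by 0.14.

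Among the genes the naming rule selected, those that rose most, besides Meg3, began with Car8, a carbonic anhydrase-related protein that lacks enzyme activity, at 4.52-fold (log2 difference 2.18, SE 0.15). Sntg1, a syntrophin, rose 4.21-fold (2.07, SE 0.12), the cadherin gene Cdh6 3.85-fold (1.94, SE 0.18) and the secreted protein gene Coch 3.66-fold (1.87, SE 0.13). Dgkb, a diacylglycerol kinase gene, rose 3.25-fold (1.70, SE 0.13). The monooxygenase-like gene Moxd1 rose by 1.57 (SE 0.18) on the log2 scale, the receptor phosphatase gene Ptprm by 1.42 (SE 0.20), the matrix gene Matn2 by 1.42 (SE 0.13), the ectonucleotidase gene Enpp3 by 1.38 (SE 0.13), the transcriptional cofactor gene Dach2 by 1.37 (SE 0.11) and the growth factor gene Fgf9 by 1.22 (SE 0.16). C130026I21Rik, which the rule leaves out and which was chosen after its value was seen, was higher by 2.15 (SE 0.24) with 1 probe set. Limma adjusted p-values of the genes the rule selected ran from 0.00150 for Sntg1 to 0.0221 for Ptprm. The brightest probe set gave 0.05 for Matn2 and 0.01 for Enpp3, so these calls rest on their other probe sets. Of the 24 genes that the rule took for the size of their differences, 16 were called whichever array was left out.

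Genes of antigen presentation and the interferon response were lower together. All 13 measured genes of the MHC class I presentation list had negative differences, with a median of -0.85, and 4 were called lower, or 10 adjusted over the list alone (camera adjusted p = 2.80e-16). H2-K1, a classical class I heavy chain, fell by 1.32 (SE 0.13) on the log2 scale, and B2m, its invariant light chain, fell by 1.22 (SE 0.19). The other called members, chosen after their values were seen, were H2-Q7 (-0.81, SE 0.12) and the immunoproteasome gene Psmb8 (-1.10, SE 0.16). H2 genes resemble each other closely and their probes can share signal, so their separate values are uncertain. Of 24 interferon response genes, 5 were called lower and 0 higher (median -0.29; camera adjusted p = 5.05e-09), or 12 lower and 1 higher adjusted over the list alone. Rsad2, an antiviral enzyme, fell by 1.19 (SE 0.15) and Oasl2 by 1.14 (SE 0.19), and the RNA sensor genes Ifih1 and Ddx58, chosen after their values were seen, fell by 1.13 (SE 0.13) and 1.08 (SE 0.11). With 1 array left out at a time, H2-K1 was called in 5 of 6 fits, B2m and Rsad2 in 2 and Oasl2 in 1. These 2 lists share 2 genes, and they are the 2 lists that stayed past the threshold with an estimated correlation (adjusted p = 0.0419 with an estimated correlation for each).

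The cholesterol synthesis list was lower (median -0.32, 19 of 20 members negative; camera adjusted p = 3.74e-10). No single member passed the genome-wide test, and 8 were lower adjusted over the list alone. Its brightest members were Insig1, a sterol sensor (-0.19, SE 0.24), and Fdft1, squalene synthase (-0.43, SE 0.14). The call was lost with an estimated correlation (adjusted p = 0.278 with an estimated correlation). Both arrays that stood apart also read lower for this list than the others of their group, by a median of -0.33 for vector replicate 2 and -0.11 for Meg3 replicate 1. Without them the list's median was -0.39 (camera adjusted p = 5.91e-12), and 9 members were called lower over all genes.

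Hox genes, which set position along the body axis, were lower as a list (28 measured, median -0.10; camera adjusted p = 3.39e-06), with 3 members called and 6 lower adjusted over the list alone. Hoxb9 fell by 1.97 (SE 0.16) and Hoxb5 by 1.16 (SE 0.15), and the remaining called gene was Hoxb6 (-0.99, SE 0.12), chosen after its value was seen. Hoxb5 and Hoxb6 were dim, with mean log2 values under the median of all genes (6.66) in both clones. With 1 array left out at a time, Hoxb9 was called in all 6 fits and Hoxb5 in 2. The list's adjusted p = 0.487 with an estimated correlation. Vector replicate 2 read higher for Hox genes than the others of its group by a median of 0.28, and without both arrays that stood apart the list's median was -0.06 (camera adjusted p = 0.0290). Of 29 cell adhesion genes, 3 were lower (median -0.15; camera adjusted p = 1.06e-04), or 5 adjusted over the list alone. The 3 called over all genes were the tight junction genes Cldn1 (-1.83, SE 0.12) and Ocln (-0.92, SE 0.13) and the epithelial adhesion gene Epcam (-0.73, SE 0.11). In the fits without 1 array, Cldn1 was called in all 6, Ocln in 2 and Epcam in 1. The list's adjusted p = 0.142 with an estimated correlation.

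A further set of lists passed with small shifts and few called members. Glycolysis and hypoxia genes had a median of -0.23 over 25 members (camera adjusted p = 0.00345), with the oxygen-sensing hydroxylase gene Egln3 called (-1.51, SE 0.17) and 2 lower adjusted over the list alone. Vector replicate 2 and Meg3 replicate 1 read lower for this list than the others of their group, by medians of -0.67 and -0.27. Without Meg3 replicate 1 the call was lost (camera adjusted p = 0.174), as it was without vector replicate 1 (0.338), whereas it held without vector replicate 2 (5.70e-07) and without both arrays that stood apart (median -0.28; 6.48e-05), with 6 members then called lower. The list's adjusted p = 0.556 with an estimated correlation. Immediate early genes (median -0.18, 24 members; camera adjusted p = 5.35e-04), TGF-beta signalling (-0.10, 28 members; 0.00340) and apoptosis regulators (-0.13, 24 members; 0.00558) had 0 members called by limma over all genes. Adjusted over the list alone, 2 TGF-beta genes were lower and 0 of the others. Each of these lists had an adjusted p = 0.142 with an estimated correlation. The brightest members included Dusp1 (-0.47, SE 0.39) and Jun (-0.54, SE 0.14), Id2 (-0.61, SE 0.23) and Bmpr2 (-0.05, SE 0.14), and Cycs (0.01, SE 0.22) and Mcl1 (-0.31, SE 0.18). Meg3 replicate 1 read lower for immediate early genes than the others of its group, by a median of -0.19. Vector replicate 2 did so for TGF-beta genes, by -0.09. Without both arrays that stood apart these lists had medians of -0.14 and -0.15 (camera adjusted p = 0.00218 and 0.00388). In all, 10 of 34 lists passed, all lower. Other ways of splitting the 6 arrays passed as many as 12 lists, so the number of lists carries little weight.

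**Figure D3:**
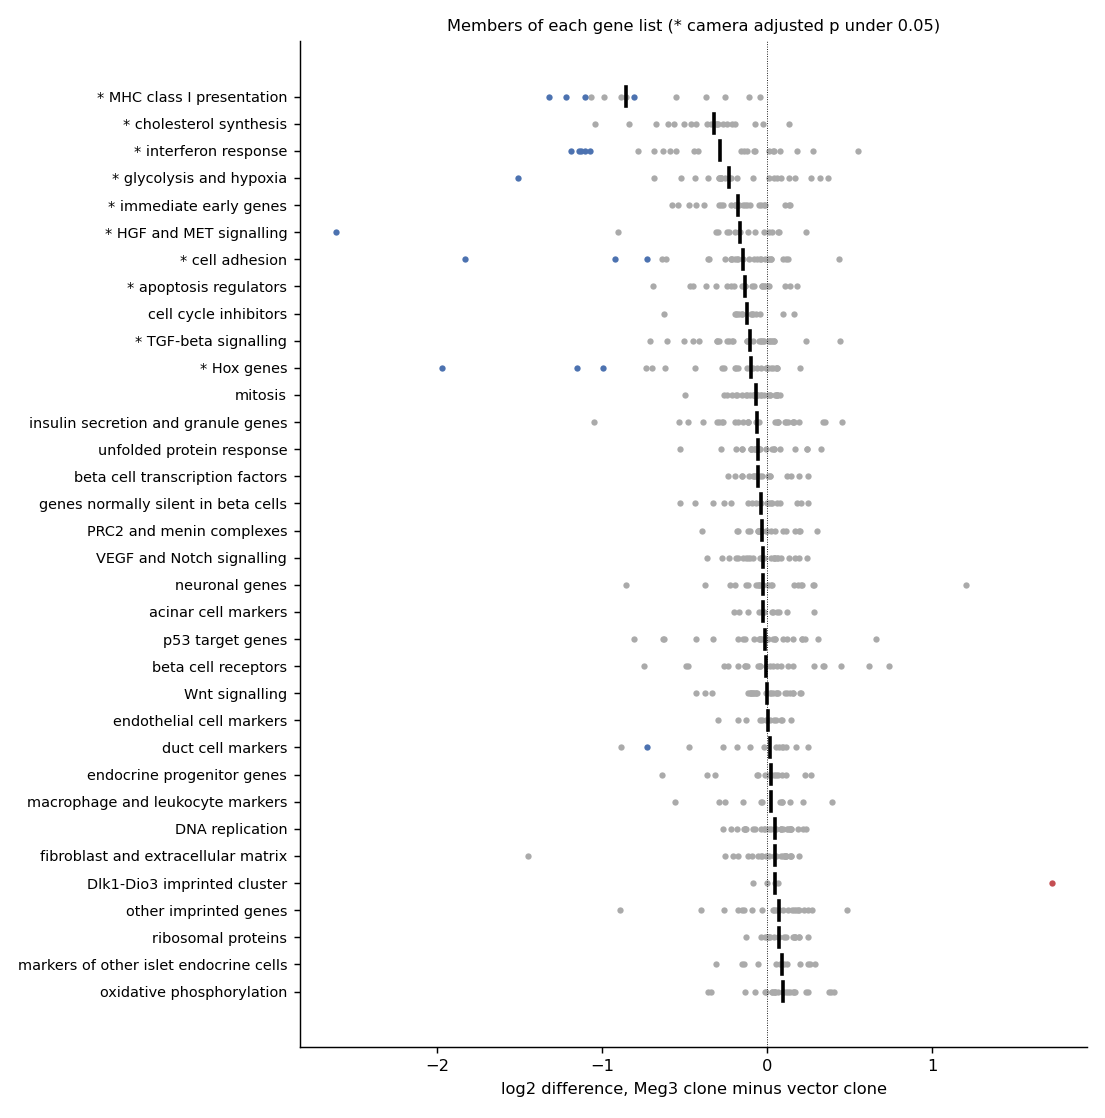
Each point is a member of a gene list, placed by its log2 difference (Meg3 clone minus vector clone), blue where called lower, red where called higher and grey where not called; black bars mark list medians. All 13 MHC class I presentation genes lie below 0 with a median of -0.85, while the median of the beta cell transcription factors is -0.05.

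The lists of p53 targets, cell cycle inhibitors, mitosis, DNA replication and PRC2 and menin complex genes did not pass camera with all 6 arrays. Among p53 targets, 0 of 27 were called by limma (median -0.01; camera adjusted p = 0.569), and 4 were lower and 1 higher adjusted over the list alone. Cdkn1a, the p21 inhibitor, differed by -0.05 (SE 0.26) and the stress cytokine gene Gdf15 by 0.23 (SE 0.17). The abundant p53 targets Ccng1 and Ei24 differed by -0.03 (SE 0.15) and -0.05 (SE 0.12). Men1, which encodes the tumour suppressor menin, differed by -0.18 (SE 0.34). Of 14 cell cycle inhibitors, 0 were called over all genes and 1 was lower adjusted over the list alone (median -0.12; camera adjusted p = 0.0562); Cdkn1b, the p27 inhibitor, differed by -0.19 (SE 0.12), Cdkn2c by 0.10 (SE 0.12) and Rb1 by -0.17 (SE 0.17). Mitosis genes (29 measured, median -0.07; camera adjusted p = 0.150) and DNA replication genes (29 measured, median 0.05; camera adjusted p = 0.995) had 0 called by limma over all genes or adjusted over the list alone. Top2a differed by -0.07 (SE 0.16), Ube2c by -0.19 (SE 0.31), Pcna by 0.02 (SE 0.11) and Prim1 by 0.14 (SE 0.13). The PRC2 and menin complex genes had 0 of 21 called over all genes or adjusted over the list alone (median -0.03; camera adjusted p = 0.995), with Suz12 at 0.02 (SE 0.14) and Mtf2 at -0.10 (SE 0.16). Without the arrays that stood apart, mitosis genes and cell cycle inhibitors passed as lists (camera adjusted p = 6.76e-04 and 0.0309), both lower, and 4 p53 targets were called lower and 1 higher over all genes, without a call for that list (0.262).

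With all 6 arrays, 0 members of the beta cell lists were called over all genes by limma. Ins2, a mouse insulin gene, stood at a mean log2 value of 12.54 ± 0.09 (SD, n = 3) in the vector clone and 12.60 ± 0.05 (SD, n = 3) in the Meg3 clone, a difference of 0.06 (SE 0.11; limma adjusted p = 1.00). The beta cell transcription factors had 0 of 18 called over all genes or adjusted over the list alone (median -0.05; camera adjusted p = 0.569). Pdx1 differed by -0.15 (SE 0.17), Mafa by -0.24 (SE 0.12), Isl1 by 0.12 (SE 0.22) and Insm1 by -0.09 (SE 0.16). Insulin secretion and granule genes had 0 of 31 called over all genes and 2 lower adjusted over the list alone (median -0.06; camera adjusted p = 0.318); Iapp, which encodes amylin, differed by -0.12 (SE 0.23) and G6pc2 by -0.05 (SE 0.14). Those 2, chosen after their values were seen, were the granule protein-folding gene Ero1lb (-1.05, SE 0.20) and the proinsulin convertase gene Pcsk1 (-0.54, SE 0.12). Without the arrays that stood apart this list passed (camera adjusted p = 0.0418), with 5 members called lower and 1 higher over all genes, and vector replicate 2 and Meg3 replicate 1 read lower for it than the others of their group, by medians of -0.33 and -0.25. Among beta cell receptors, 0 of 25 were called over all genes and 1 was higher adjusted over the list alone (median -0.01, with a test in the other direction; camera adjusted p = 0.995), with Glp1r at 0.34 (SE 0.45) and P2ry1 at -0.18 (SE 0.13).

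Markers of other cell types and states did not move as lists. Camera adjusted p-values were 0.352 for other islet endocrine cells (median 0.09) and for genes normally silent in beta cells (-0.04), 0.153 for duct cells (0.02), and 0.995 for endocrine progenitor (0.02), acinar (-0.02), fibroblast and matrix (0.05), endothelial (0.01), leukocyte (0.02) and neuronal (-0.02) genes. The 1 marker called was Epcam in the duct list, where 3 were lower adjusted over the list alone; 1 neuronal gene was lower adjusted over the list alone, and 0 in the rest. The median and the mean or test differed in sign for the endocrine progenitor, acinar, duct, fibroblast, endothelial, leukocyte and neuronal lists, all with medians near 0. Gcg, the glucagon gene, was abundant in both clones (mean log2 values 12.82 and 12.66; difference -0.15, SE 0.12). Oxidative phosphorylation (median 0.09; camera adjusted p = 0.153), ribosomal protein (0.07; 0.270), unfolded protein response (-0.05; 0.534), Wnt (-0.00; 0.938), VEGF and Notch (-0.03; 0.569) and other imprinted genes (0.07; 0.451) had 0 called over all genes by limma, and 1 other imprinted gene was lower adjusted over the list alone. The Dlk1-Dio3 cluster had Meg3 alone called among 5 measured (camera adjusted p = 0.150), and the list passed without the arrays that stood apart (median 0.16, camera adjusted p = 0.0488). The list holds Meg3 itself, which the plasmid carries, and was not tested without it, so that pass says nothing about its other members.

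Along the chromosomes, expressed genes of chromosomes 13 and 14 were lower in the Meg3 clone. The median log2 difference was -0.17 for 381 genes of chromosome 13 and -0.19 for 373 genes of chromosome 14, with 78.2% and 80.2% of genes below 0. Chromosome 3 followed with -0.12 (481 genes), and chromosome 9 with -0.07 (560 genes). On chromosome 9 the shift began within the chromosome. From the block starting at Tln2 to the far end the block medians lay between -0.27 and -0.18, and before it between -0.02 and 0.06. On chromosome 13 the last block, from Iqgap2 on, had a median of -0.03. Medians of the 16 other chromosomes lay between -0.01 and 0.03, but the far end of chromosome 4 was higher in the Meg3 clone, with block medians of 0.13 from Dhdds, 0.06 from Otud3 and 0.15 from Clstn1 on. None of 10000 random sets of matched genes, which take no account of genes that vary together, reached the median of chromosomes 3, 9, 13 or 14. The random sets also marked small shifts: the median of chromosome 4 (0.025) lay above all of them, and that of chromosome 11 (0.019) at or above 99.97%. This comparison therefore does not single out chromosomes 3, 9, 13 and 14. Expression was then taken as 1 value per array and chromosome, relative to the array's median over all expressed genes. The difference in it had a limma adjusted p = 0.0880 for chromosome 14, 0.122 for chromosomes 13 and 9 and 0.308 for chromosome 3, so no chromosome passed that test. The 9 pairs of a Meg3 and a vector array were likewise taken relative to each pair's median over all expressed genes. Of these, 8 were negative on chromosome 3 and all 9 on chromosomes 9, 13 and 14.

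**Figure D4:**
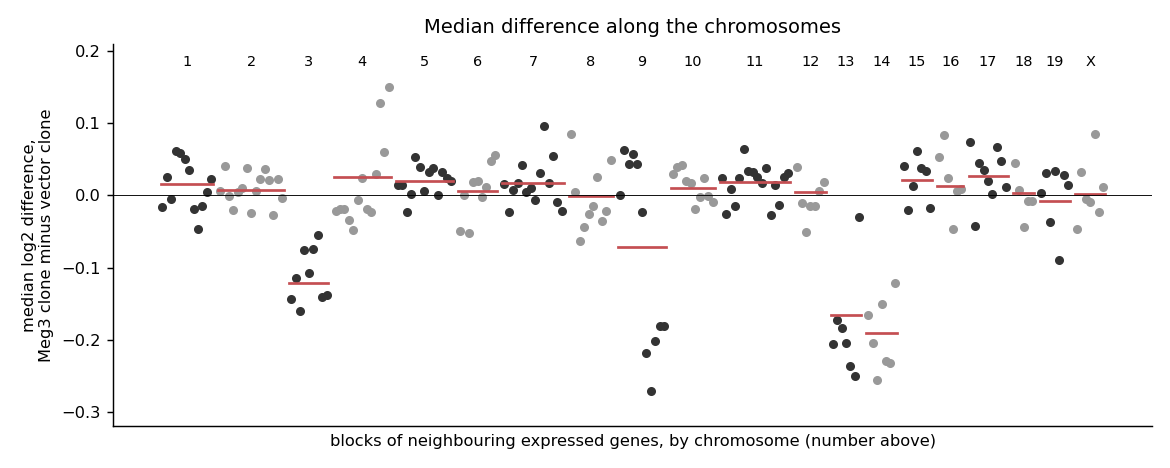
Each point is the median log2 difference (Meg3 clone minus vector clone) of a block of at least 50 neighbouring expressed genes, in gene order of assembly GRCm38.p6, and red lines mark chromosome medians. The medians of chromosomes 13 (-0.17), 14 (-0.19) and 3 (-0.12) are the lowest, the far blocks of chromosome 9 lie between -0.27 and -0.18, and the last block of chromosome 4 (0.15) lies highest.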

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

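Named genes past the threshold kept their direction under every gene-level alternative run for them, except Prkd3, but how many genes pass depends on the arrays and the model. Leaving out vector replicate 2 and Meg3 replicate 1 together, subtracting chromosome medians and dropping Met or the H2 genes from a list were chosen after seeing the data. The counts of higher, lower and 2-fold genes (41, 95 and 90) stayed within 1.5 times under centring, renewed quantile normalization, the filter on dim genes, trend with robust estimation and chromosome medians. With the brightest probe set they were 12, 28 and 40; against a 1.5-fold difference 5, 10 and 15; for probe sets tested singly 1, 7 and 8. The ordinary linear model called 0, 0 and 0 after Benjamini-Hochberg adjustment (697 higher and 846 lower at an unadjusted p under 0.05), with few degrees of freedom per gene. Array weights gave 1063 higher and 1619 lower, but they set vector replicate 3 at 10.5 against 1.08 and 0.13 for vector replicates 1 and 2. The vector group then rested mostly on 1 array, so these counts carry little weight. Leaving out both arrays that stood apart gave 292 and 819. Leaving out each array in turn gave 8 to 78 higher, 14 to 271 lower and 22 to 124 at 2-fold. The highest came without vector replicate 2 and the lowest without Meg3 replicate 3; the higher counts without vector 1, vector 3, Meg3 1 and Meg3 2 were 17, 13, 18 and 9, and the lower counts 42, 37, 61 and 17.

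Whether replicate numbers pair the samples cannot be told. Deviations of same-numbered cultures from their group mean correlated at -0.61, -0.63 and 0.28 over genes, and no vector culture matched its own number best. The arrays that stood apart, vector replicate 2 and Meg3 replicate 1, carry different numbers and shape these values, which therefore decide nothing about pairing. With a replicate block 11 genes were higher and 19 lower, 30 of them 2-fold, and 10 lists passed.

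Meg3 was higher in each of the gene-level settings run for it, whereas 0 of its 5 probe sets passed singly in limma and 1, dim in both clones, was lower (-0.22). Its adjusted p in limma was 0.241 with the brightest probe set (log2 difference 2.02), 0.203 in the ordinary model (1.72) and 0.0666 without Meg3 replicate 3 (1.74). Without each array the difference ran from 1.55 to 1.88. Over these gene-level alternatives its limma adjusted p ran from 1.84e-06, with the array weights that favoured vector replicate 3, to 0.241. Among the named genes past the threshold only Prkd3 reversed, at 0.14 with the brightest probe set. Over the alternatives and the named genes other than Meg3, 1326 outcomes were on the same side of the threshold, 111 were weaker and 18 became calls. Lists not past the threshold passed it in 13 outcomes. Apart from the loss of arrays or degrees of freedom, the cause was not tested. Signal over background was not assessed.

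Lists past the threshold numbered 10, against 2 with an estimated correlation and 5 with fry, and 8 to 15 without each array. With the estimated correlation the adjusted p was 0.278 for HGF and MET and for cholesterol, 0.142 for apoptosis, TGF-beta, adhesion and immediate early genes, 0.556 for glycolysis and 0.487 for Hox. With fry it was 0.137 for HGF and MET, cholesterol, Hox and immediate early genes and 0.523 for glycolysis. With the brightest probe set it was 0.0596 for apoptosis, 0.0845 for TGF-beta and 0.274 for glycolysis. Without each array, HGF and MET ran from 2.32e-04 to 0.108 (lost without vector replicate 3 at 0.0868 and Meg3 replicate 1) and glycolysis from 5.70e-07 to 0.338 (lost without vector replicate 1, and without Meg3 replicate 1 at 0.174). Without Met the HGF and MET list had 0.0893. MHC class I presentation and the interferon response passed under every list setting run, MHC also without H2 genes (1.79e-08).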

Other observations

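The gene families of this paragraph were chosen after their values were seen, and no enrichment was tested. Among protocadherins, 21 of 22 beta-cluster genes had negative differences (median -0.30) and 4 were lower, whereas the neighbouring alpha cluster had a median of 0.09 and the gamma cluster -0.09, with 0 called by limma in each.

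The tests of the patterns that follow, and the splits of the arrays, were chosen after the results they bear on were seen. In the split by clone 41 genes were higher, 95 lower and 90 at 2-fold, and the highest count by limma in the other splits of the 6 arrays into 3 and 3 was 0 for each (1 of 10 splits gave as many). For lists past the threshold the split by clone gave 10 and the highest other 12, and 3 of 10 splits gave as many. The splits with 12 set vector replicate 2 and Meg3 replicate 1 together against vector replicates 1 and 3, and 1 of them had 4016 genes at an unadjusted p under 0.05 against 1421 for the clones, which points to a structure of the samples. With 10 splits no share under 0.05 can be reached.

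Vector replicate 2 and Meg3 replicate 1 differed from their group in the same way (Spearman correlation 0.58 across genes, which are not independent). The 7 measured mitochondrially encoded genes, chosen after their values were seen, read higher on these arrays than on the others of their group, by medians of 0.64 and 0.61. Uneven signal along transcripts, as degraded RNA leaves, stays open: slopes along single genes had an SD of 0.73 and 0.46 in these arrays against 0.23 to 0.31 in the others, and removing the small median gradient moved almost nothing (ratio of SDs 0.999), which decides nothing. A swap between these arrays is argued against: of 1111 genes called without them, vector replicate 2 lay on the vector side for 61.8% and Meg3 replicate 1 on the Meg3 side for 78.5%, and for 134 genes with 2-fold differences the shares were 81.3% and 91.0%. A shared handling or hybridisation batch may remain, for which the labels give no information, and the sequence composition of the probes was not tested.

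Whether lower expression over chromosome 14 and all but the last block of chromosome 13 reflects fewer copies in the Meg3 clone stays open. The share of genes below 0 on chromosomes 13 and 14 exceeded that on 16 other chromosomes by 32.4 percentage points, and the medians were lower in dim and bright genes. All 9 pairs of a Meg3 and a vector array, relative to their medians over all expressed genes, went the same way for each. These values restate the pattern these chromosomes were picked for and decide nothing about copies. Without the arrays that stood apart the median on 13 and 14 minus that of the others was still -0.21. A composition trend that follows the shift of vector replicate 2 is argued against. That array's median difference from vector replicates 1 and 3 was -0.06 and -0.09 on chromosomes 13 and 14. On chromosomes 12, 18 and 1 it was -0.07, -0.09 and -0.10, yet their clone differences were 0.005, 0.003 and 0.015. Without the arrays that stood apart those clone differences were -0.03, -0.04 and -0.02, against -0.22 and -0.25 on 13 and 14. Chromosome 3, at -0.04 for vector replicate 2, had a clone difference of -0.12. A trend of another kind stays open. Relative to the median chromosome vector replicate 2 shifted X most (0.07, where the others lay between -0.31 and -0.04), and the clone difference there was 0.00178. That is imprecise: the 9 array pairs, relative to their medians over all expressed genes, ran from -0.19 to 0.23. The difference in 1 value per array, taken likewise, had an SE of 0.08. Meg3 replicate 1 shifted X upward as well (0.14), so such a trend could cancel there between the clones, and chromosome X decides nothing. Over the 20 chromosomes the shift of vector replicate 2 and the clone difference correlated at -0.502 (Spearman). Vector replicate 2 enters both values with opposite signs, which by itself pushes this correlation below 0, so it decides nothing. No DNA measurement was analysed here.

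Lower MHC class I and interferon genes were not limited to H2 genes with near-identical copies, since the 8 other MHC presentation genes had a median of -0.70. Lower chromosomes do not account for them either: the 30 members of both lists outside chromosomes 3, 9, 13 and 14 had a median of -0.50. No mechanism was tested, and whether the difference follows from Meg3 or from the choice of clones is open, because each group is 1 clone.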
